A study of Mus musculus with 8 samples.

How the data were processed

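RNA was extracted from neutrophils sorted from the blood of 8 mice and sequenced on an Illumina platform, per the labels' protocols. The labels give 2 genotypes of 4 mice each, and each library comes from 1 mouse per the design text. The submitters' processing notes name kallisto, DESeq and the genome build GRCm38, without versions, and the transcript set is not given in the sources used here. The authors deposited 1 table per library, with the length and effective length of 118783 transcripts and 2 measurements per the file headers. The first is the estimated count of reads per transcript that kallisto assigns by expectation maximization, deposited without normalization. The second is TPM, deposited by the authors as kallisto divides each count by the effective length and scales the values to a fixed sum. Reads that fit several transcripts or paralogs are split between them by the estimate, so values of single transcripts and of near-identical genes carry an uncertainty that these tables do not hold, since bootstrap replicates were not used here.

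Transcripts were joined to genes by their Ensembl identifiers without version, in the GENCODE release M21 annotation of GRCm38, which matched 116622 of 118783 transcripts (98.2%) and gave 35865 genes. Unmatched transcripts held 0.644% to 0.723% of the counts of a library and were left out. Gene coordinates come from the same annotation and count from 1. Estimated counts were summed per gene and rounded to whole numbers. Depth ran from 57521693 to 87445336 estimated counts per library. Intervals and floors on counts cover counting error only, because reads without molecular identifiers are not independent molecules. The lowest chi-square per gene between any pair of the 28 library pairs was 83.1, so no library was a copy of another.

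The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05, over all 8 libraries with genotype as the factor and without covariates. Fold changes are heterozygous over wild type, and their standard errors derive from the quasi-likelihood F. Group means are in TMM-scaled CPM, counts scaled to library size. The biological coefficient of variation was 27.2%. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists. A list score is the mean over its genes of log2 CPM minus the gene's mean over the 8 libraries. Shares of counts and list scores were compared by exact two-sided permutation over all assignments of 4 libraries out of 8, which can give no p below 0.0286. Shared 31-base words were counted in the annotation's transcripts on both strands with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

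The 25 gene lists, the main test, its alternatives and the rule for named genes were fixed before the data were examined. Of the list members, 1 (Pvt1) was not found among the genes. Trp53, Cdkn1a and Mdm2 are always named. In each direction the rule adds the 10 genes with the largest change among those that pass, have a mean of at least 1 CPM and do not overlap between genotypes. Where fewer than 10 genes qualify, it adds the 10 with the smallest p. Predicted genes, immune receptor segments and pseudogenes are counted and not named. From each list it takes up to 4 members with the smallest p. The text gives examples from the 110 genes that the rule selects.

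Alternatives were median-ratio size factors, no low-count filter (a total above 0), a minimum mean of 5 CPM, length-scaled TPM counts, the replicate number as a block, leaving out hemoglobin and mitochondrial genes, limma voom with sample quality weights, limma trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM, DESeq2 1.42.0, non-robust fits, a threshold of 0.1, estimated correlations and fry for the lists, and leaving out each library. Chosen after seeing the data were the fit without wild-type library 1 and heterozygous library 4 together, the test per transcript and the counts around Trp53. On data simulated from the means, library sizes and dispersions of these 13982 genes, with 3 runs of 200 changed genes, edgeR recovered 39.2% of 2-fold and 83.6% of 4-fold changes but 1.6% of 1.5-fold changes, and 10.7% of its calls were false. DESeq2 recovered 10.1%, 52.5% and 92.8% of 1.5-fold, 2-fold and 4-fold changes with 25.6% false calls, and voom recovered 1.6%, 35.3% and 80.2% with 9.4% false calls. In these runs, where genes vary independently, camera with the preset correlation called a shifted interferon list in 3 of 3 runs and 0 of 72 unshifted lists. In the libraries themselves the estimated correlation within a list reached 0.782, so the 0 of 72 does not carry over to them.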

Results

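Neutrophils were sorted from the peripheral blood of C57BL/6J mice 1 day after a single injection of doxorubicin at 15 µg/g, and their RNA was sequenced. Doxorubicin is an anthracycline that damages DNA and is toxic to heart muscle. The mice were wild type (n = 4) or heterozygous for loss of Trp53 (n = 4), the gene of the p53 tumour suppressor. The titles of the 4 heterozygous samples also carry a knock-out tag, and the genotype field, which calls them heterozygous, was followed. The title of the series places the comparison in therapy-related clonal hematopoiesis, where Trp53-deficient blood cells are studied for a stronger cytotoxic response of neutrophils in the heart. Every mouse had received the drug, so the comparison is between genotypes under doxorubicin, and the effect of the drug itself was not analysed here.

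The libraries held 63736308, 60456419, 69570240 and 57521693 estimated counts in wild-type mice 1 to 4 and 87445336, 87110276, 83260737 and 71559922 in heterozygous mice 1 to 4. All 4 heterozygous libraries were deeper than all 4 wild-type libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.486 after Benjamini-Hochberg adjustment over 17 library measures). The neutrophil calprotectin genes S100a9 and S100a8 took 3.8% and 3.7% of the counts on average, ahead of Actb at 1.81%. Hemoglobin transcripts, which come from red cells, took 2.20% ± 1.43 (SD, n = 4) of the counts in wild-type libraries and 2.84% ± 1.12 (SD, n = 4) in heterozygous ones. Markers of monocytes and macrophages took 0.376% ± 0.0178 and 0.365% ± 0.0147 (SD, n = 4 each). Markers of B cells took 0.0113% ± 0.0034 and 0.0124% ± 0.00081, and those of T and NK cells 0.0016% ± 0.00015 and 0.0021% ± 0.0011. By exact permutation tests 1 of the 17 measures had an unadjusted p under 0.05 and 0 an adjusted one, a threshold that no single measure can pass with 4 libraries per genotype.

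Trp53 transcripts were less abundant in every heterozygous library than in any wild-type library. Trp53 (chromosome 11, 69580359 to 69591873, GRCm38) averaged 6.04 CPM ± 0.47 (SD, n = 4) in wild-type mice and 3.53 CPM ± 0.67 (SD, n = 4) in heterozygous mice, a ratio of 0.586. The log2 fold change was -0.77 with a standard error of 0.17. The exact two-sided permutation p of Trp53 in TPM was 0.0286, the smallest possible. In the test across all genes the adjusted p was 0.600 with edgeR's quasi-likelihood test and 0.032 with DESeq2. The direction held in each of 18 alternative fits, whose adjusted p ran from 0.032 to 0.997. Of its 31-base words, 10.2% also occur in transcripts of other genes, 8.8% in the pseudogene Trp53-ps.

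Few other genes differed between the genotypes past the threshold. Of 13982 genes tested, 4 rose in heterozygous neutrophils and 0 fell at a false discovery rate of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 667 genes, where 699 are expected with no effect. That count depended on the fit. It was 2421 with limma voom on the same genes and libraries, and ran from 434 to 1314 when 1 library was left out. Its nearness to 699 therefore does not show that there was no effect. Capn11, which encodes a calpain protease, was nearly silent in wild-type neutrophils, with 1 count in all 4 libraries together, and had 487 counts in heterozygous ones. The ratio of its rates was 356 with an exact 95% counting interval of 63.7 to 14100, and its heterozygous libraries held 1.45 CPM ± 0.25 (SD, n = 4; adjusted p = 0.000118). Eps8l1, a relative of the actin regulator Eps8, rose from 2.19 CPM ± 0.18 to 5.14 CPM ± 0.45 (SD, n = 4 each; log2 fold change 1.23 ± 0.15 SE, edgeR adjusted p = 0.0271). Sgip1, an endocytic adaptor gene, rose from 18.9 CPM ± 3.0 to 39.9 CPM ± 4.9 (SD, n = 4 each; log2 fold change 1.08 ± 0.14 SE, edgeR adjusted p = 0.0273). The fourth gene, Gm1821, is a predicted processed pseudogene outside the rule for named genes and was named after its values were seen. It rose from 167 CPM ± 17 to 322 CPM ± 30 (SD, n = 4 each; log2 fold change 0.94 ± 0.12 SE, edgeR adjusted p = 0.0271), and 86.3% of its 31-base words are shared with the ubiquitin gene Ubb, so its counts and those of Ubb cannot be separated with certainty. Ubb lies on chromosome 11 at 62551171 to 62553213 and averaged 5308 CPM ± 317 in wild-type and 4684 CPM ± 188 in heterozygous libraries (SD, n = 4 each; edgeR adjusted p = 0.873).

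Capn11 lies on chromosome 17 at 45630204 to 45659325, Eps8l1 on chromosome 7 at 4460674 to 4480487, Sgip1 on chromosome 4 at 102741297 to 102973628 and Gm1821 on chromosome 14 at 46084028 to 46085000. For all 4 genes the values of the genotypes did not overlap, which 511 of the tested genes showed (3.65%, where chance gives 2.86%). Capn11 was called in 8 of the 8 fits that left out 1 library each. Eps8l1 was called in 1 of these fits, without heterozygous library 4, Sgip1 in 1, without heterozygous library 1, and Gm1821 in 2, without heterozygous library 1 or 4. The adjusted p reached 0.171, 0.186 and 0.186 for the 3 genes in the other fits, while their log2 fold changes ran from 1.18 to 1.29, 0.99 to 1.15 and 0.87 to 0.98 over all 8 fits.

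**Figure D1:**
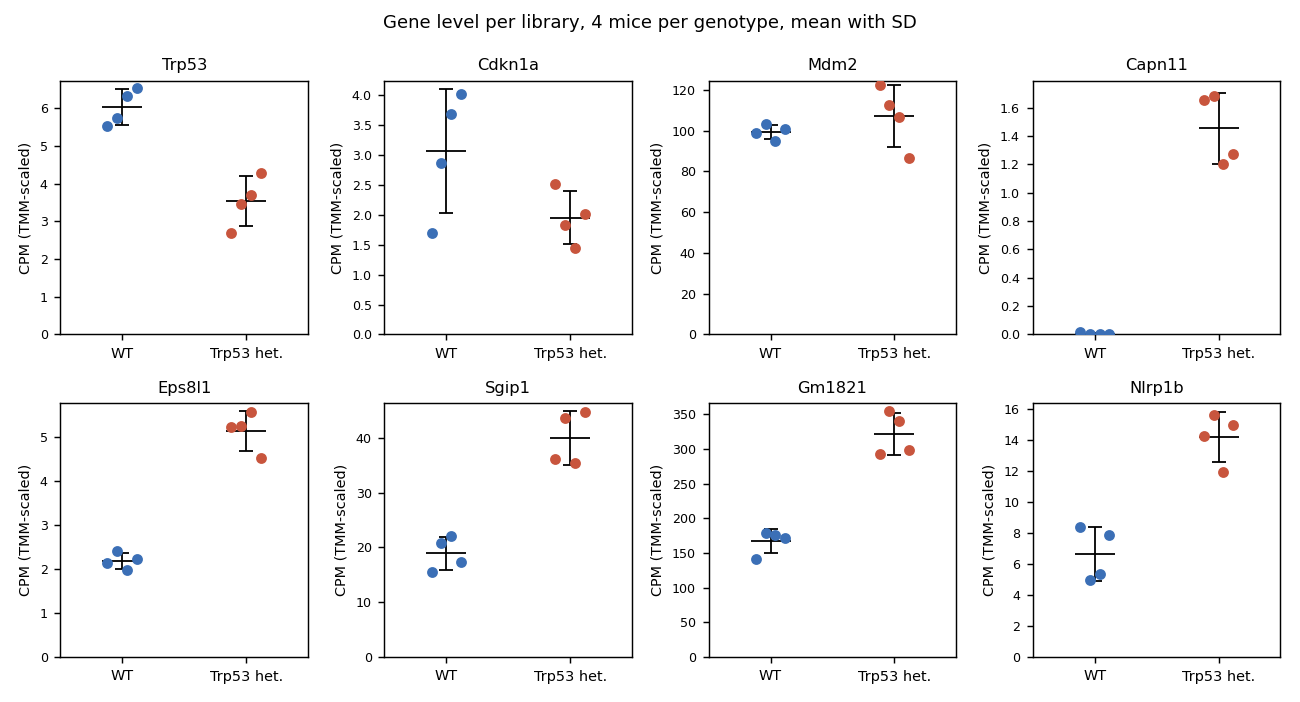
Level of 8 genes in each library, in TMM-scaled CPM (vertical axis from 0 in each panel), for wild-type (WT, blue) and Trp53 heterozygous (red) mice. Points are libraries, horizontal bars are means and error bars are SD (n = 4 per genotype), and the genotypes do not overlap for Trp53, Capn11, Eps8l1, Sgip1, Gm1821 and Nlrp1b, while they overlap for Cdkn1a and Mdm2.

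The genes with the next smallest p-values did not pass the threshold of edgeR's test. Cdk5rap1, which encodes an enzyme that modifies mitochondrial transfer RNA, averaged 3.16 CPM ± 0.95 in wild-type and 8.13 CPM ± 1.14 in heterozygous libraries (SD, n = 4 each; edgeR adjusted p = 0.0997). The inflammasome sensor gene Nlrp1b averaged 6.64 CPM ± 1.75 and 14.2 CPM ± 1.6 (SD, n = 4 each; edgeR adjusted p = 0.193). The corepressor subunit gene Gps2 averaged 42.4 CPM ± 1.6 and 28.3 CPM ± 2.2, and Kctd11 averaged 46.8 CPM ± 2.6 and 28.4 CPM ± 4.9 (SD, n = 4 each; edgeR adjusted p = 0.193 and 0.273). Plscr3, a phospholipid scramblase gene, averaged 1.64 CPM ± 0.35 and 3.52 CPM ± 0.47, although 25.9% of its 31-base words are shared with Tnk1 (edgeR adjusted p = 0.250). Jade1 had a log2 fold change of -0.88 and Cpne8 of 1.30 (edgeR adjusted p = 0.374 and 0.387). DESeq2 called 14 genes, 10 higher and 4 lower, among them the 4 above, Trp53 and these 7 genes. Of the 14, 6 lie within 20 Mb of Trp53, with Trp53 itself counted among the 6.

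Nlrp1b, Gps2, Plscr3 and Kctd11 all lie within 5 Mb of Trp53 on chromosome 11, and the distribution of low p-values around the gene was therefore counted after the data had been examined. Within 20 Mb of Trp53, 17 of 469 tested genes (3.62%) had an unadjusted p under 0.01 in edgeR's test, Trp53 included, 9 with higher and 8 with lower values in heterozygous mice. Within 5 Mb it was 8 of 136 (5.88%). On the rest of chromosome 11 it was 6 of 591 (1.02%), and on the other chromosomes 97 of 12922 (0.751%). The inflammasome gene Nlrp1a, next to Nlrp1b, averaged 24.6 CPM in wild-type and 12.8 CPM in heterozygous libraries, and the olfactory receptor gene Olfr395 averaged 0.516 and 1.89 CPM. These 2 genes were named after their values were seen.

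**Figure D2:**
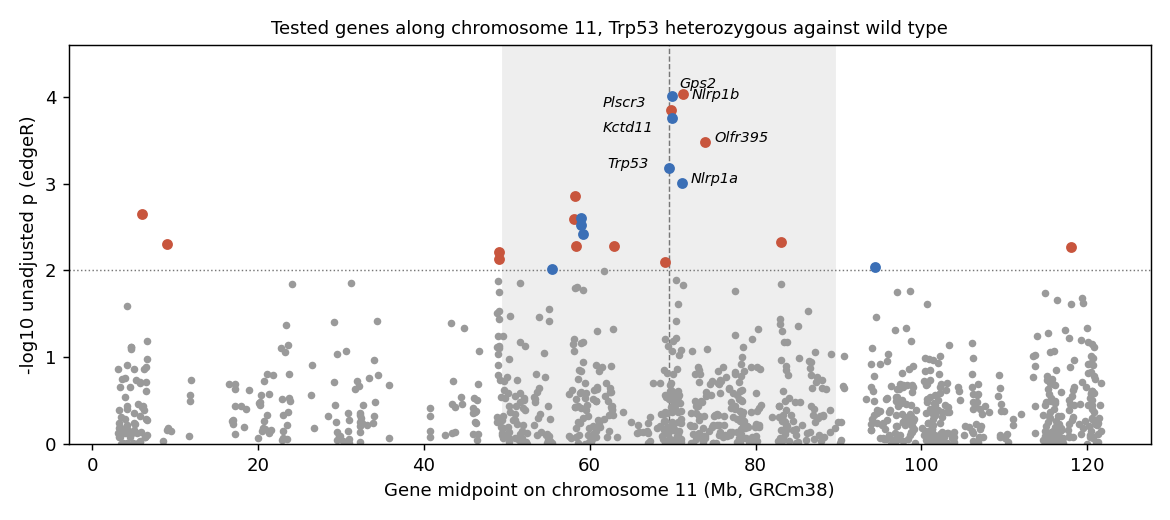
Each point is a tested gene on chromosome 11, placed by its midpoint (horizontal axis, Mb, GRCm38) and by the negative log10 of its unadjusted edgeR p (vertical axis). Coloured points have p under 0.01 (dotted line; red higher and blue lower in Trp53 heterozygous mice), the dashed line marks Trp53 and the grey band the 20 Mb to each side, which holds 17 of the coloured points.

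The same counts were also tested per transcript, an analysis added after the data were examined. Of 38655 transcripts, 3 rose and 1 fell (edgeR, false discovery rate 0.05). Both Nlrp1b transcripts among them moved in opposite directions. The coding transcript Nlrp1b-204 averaged 4.53 CPM ± 1.20 (SD, n = 4) in wild-type libraries. It was estimated at 0 in all 4 heterozygous libraries, at least 498-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0147). The bound covers counting error only. Reads that fit several Nlrp1b transcripts may have been assigned to another of them, so the estimate does not establish that the transcript was lost. The transcript Nlrp1b-205, annotated for nonsense-mediated decay, rose from 1.38 CPM ± 0.48 to 12.3 CPM ± 1.7 (SD, n = 4 each; edgeR adjusted p = 0.0147). Capn11-201 was at 0 in all 4 wild-type libraries and at least 119-fold higher in heterozygous ones against the same floor (edgeR adjusted p = 0.0274). Gm1821-202 rose from 59.0 CPM ± 11.5 to 229 CPM ± 29 (SD, n = 4 each; edgeR adjusted p = 0.0147), whereas Gm1821-201 averaged 108 CPM in wild-type and 92.4 CPM in heterozygous libraries. The number of transcripts called was 0 to 3 when 1 library was left out, with 0 without wild-type library 3 or 4 or heterozygous library 2 or 4, 1 without wild-type library 1 or 2, and 2 without heterozygous library 3. It was 0 without wild-type library 1 and heterozygous library 4 together.

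Genes that p53 activates did not pass as a list. Of 37 tested members of a fixed list of p53 targets, 16 had higher and 21 lower values in heterozygous neutrophils, with a median log2 fold change of -0.06 (camera adjusted p = 0.391). When 1 library was left out the median ran from -0.12, without wild-type library 1, to 0.03, without wild-type library 4, and the list passed in 0 of the 8 fits. Neither over all genes tested nor adjusted over the list alone did any member pass in edgeR's test, and 3 had an unadjusted p under 0.05. The cell cycle inhibitor gene Cdkn1a averaged 3.07 CPM ± 1.03 in wild-type and 1.95 CPM ± 0.45 in heterozygous libraries (SD, n = 4 each), with a log2 fold change of -0.65 ± 0.27 SE (edgeR adjusted p = 0.873). Mdm2, whose product degrades p53, averaged 99.3 CPM ± 3.6 and 107 CPM ± 15 (SD, n = 4 each; log2 fold change 0.11 ± 0.12 SE, edgeR adjusted p = 0.884). The ribonucleotide reductase subunit gene Rrm2b had a log2 fold change of 0.30 and Ei24 of -0.60 (edgeR adjusted p = 0.873 for both). Of 33 genes of DNA damage signalling and repair, 22 had higher and 11 lower values (camera adjusted p = 0.744), with Brca2 at a log2 fold change of 0.54 and H2afx at -0.37. Of 28 apoptosis regulators, 16 had higher and 12 lower values (camera adjusted p = 0.451; median below 0 without wild-type library 3 or heterozygous library 1, at -0.02 and -0.03), with Casp7 at 0.35, Bmf at 0.67 and Bax at -0.37. No member of these 2 lists passed over all genes tested or adjusted over the list alone.

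Of 4 lists of neutrophil genes, 1 passed with the preset correlation, that of secondary and tertiary granules. Of its 21 genes, 19 had lower values, with a median log2 fold change of -0.21 (17 of 21 and -0.08 on the log2(TPM + 1) scale). On that scale, here and below, the median over all genes tested was 0.052, against 0.0015 in the main fit. The list passed camera's test with a preset inter-gene correlation of 0.01 (adjusted p = 0.00653) and lost it with an estimated correlation (adjusted p = 0.713), and no member of it, or of the 3 other neutrophil lists given here, passed over all genes tested or adjusted over the list alone. Lcn2, which encodes the iron-binding granule protein lipocalin 2, averaged 4849 CPM ± 799 in wild-type and 3560 CPM ± 420 in heterozygous libraries (SD, n = 4 each; edgeR adjusted p = 0.873), without overlap between genotypes. Chil3 averaged 135 CPM ± 21 and 99.0 CPM ± 18.0 (SD, n = 4 each; edgeR adjusted p = 0.873). Without wild-type library 3 or heterozygous library 4 the list no longer passed (highest adjusted p = 0.235), with medians of -0.12 and -0.15, and the median was -0.33 without heterozygous library 3. The lists of oxidative stress, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins and platelets, given below, were also lower and passed in the same test. Of the 10 genes of the NADPH oxidase, the enzyme that makes superoxide, 7 had lower values (camera adjusted p = 0.0572). That list passed in 4 of the 8 fits without 1 library, those without wild-type library 2 or heterozygous library 1, 2 or 3 (lowest adjusted p = 0.0188), and its median ran from -0.19 to -0.01, the latter without heterozygous library 4 (adjusted p = 0.656). Its membrane subunit gene Cyba averaged 847 CPM ± 47 and 724 CPM ± 70, and the cytosolic subunit gene Ncf2 averaged 865 CPM ± 43 and 784 CPM ± 84 (SD, n = 4 each). Of 7 primary granule genes, 4 had lower values (3 of 6 on the log2(TPM + 1) scale; camera adjusted p = 0.267), with Prtn3 at a log2 fold change of -0.44 and Srgn at 0.13. Of 32 genes of neutrophil maturity and surface receptors, 21 had lower values (median -0.06, or 14 of 32 and 0.02 on the log2(TPM + 1) scale; camera adjusted p = 0.0858). It passed without wild-type library 1 or heterozygous library 1 or 2 (medians -0.10, -0.13 and -0.10, lowest adjusted p = 0.00282), and its median was 0.0028 without heterozygous library 4. Among its genes were S100a9 at a log2 fold change of -0.25 and S100a8 at -0.23. The mean score of the maturity list was lower in all 4 heterozygous libraries than in any wild-type library (exact permutation p = 0.0286, adjusted p = 0.476 over 25 lists).

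Genes of the type I interferon response were higher in heterozygous neutrophils as a list, but with a wide spread between mice. All 45 tested members had higher mean values, with a median log2 fold change of 0.36, and 15 had an unadjusted p under 0.05 in edgeR's test. The list passed with the preset correlation (camera adjusted p = 8.0e-14), and it did not with the correlation of 0.725 estimated from these libraries (adjusted p = 0.713, unadjusted 0.149). Over all genes tested 0 members passed, and adjusted over the list alone 1 did, Phf11b, at 0.660 CPM ± 0.066 in wild-type and 1.58 CPM ± 0.60 in heterozygous libraries (SD, n = 4 each; edgeR adjusted p = 0.0359 over the list). The ubiquitin ligase gene Herc6 averaged 225 CPM ± 29 and 363 CPM ± 108, the interferon-inducible GTPase gene Ifi47 413 CPM ± 70 and 649 CPM ± 176, and the guanylate-binding protein gene Gbp3 105 CPM ± 23 and 160 CPM ± 34 (SD, n = 4 each). Per library, the mean deviation of the list on the log2 scale was -0.37, -0.05, -0.30 and 0.01 in wild-type mice 1 to 4 and 0.38, 0.54, 0.04 and -0.24 in heterozygous mice 1 to 4 (exact two-sided permutation p = 0.114). The list passed with the preset correlation in all 8 fits that left out 1 library, with a median log2 fold change of 0.21, without heterozygous library 2, to 0.47. Markers of monocytes and macrophages had a median log2 fold change of -0.04 and a mean of 0.07 over 21 genes (camera adjusted p = 0.726), whereas the lists of B cells, of T and NK cells and of mitochondrially encoded transcripts, given below, were higher and passed with the same preset correlation.

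**Figure D3:**
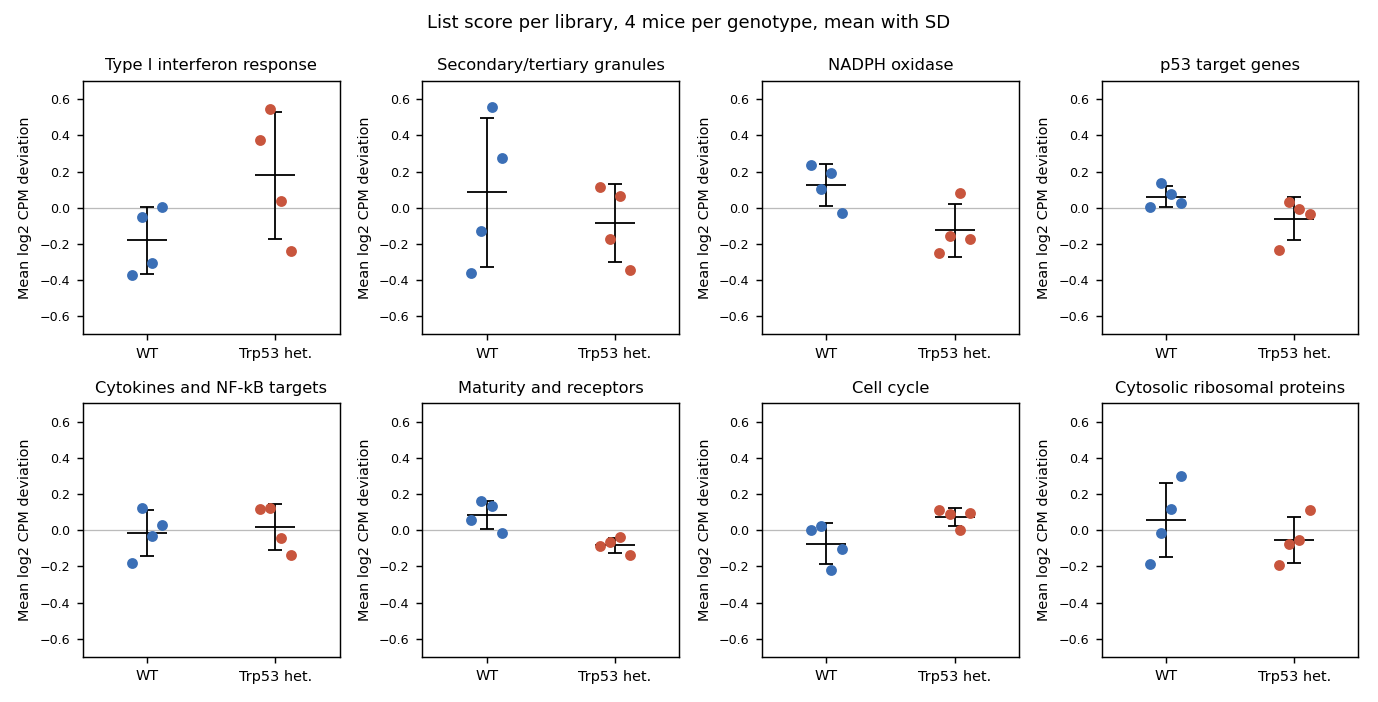
Mean log2 CPM of 8 fixed gene lists in each library, as the deviation from the mean over all 8 libraries (vertical axis, same range in each panel), for wild-type (WT, blue) and Trp53 heterozygous (red) mice. Points are libraries, horizontal bars are means and error bars are SD (n = 4 per genotype), and the interferon scores overlap between genotypes, from -0.37 to 0.01 in wild-type and from -0.24 to 0.54 in heterozygous libraries.

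Inflammatory cytokines and NF-kB targets did not pass as a list. Of 37 members, 17 had higher and 20 lower values (median -0.02, or 0.09 on the log2(TPM + 1) scale; camera adjusted p = 0.861), with the cytokine gene Il18 at 6.42 CPM ± 1.03 and 9.17 CPM ± 2.26 and the NF-kB subunit gene Relb at 24.2 CPM ± 1.6 and 18.4 CPM ± 4.3 (SD, n = 4 each; edgeR adjusted p = 0.873 for both). Of 18 genes of antigen presentation, 15 had higher values (camera adjusted p = 0.0572), with Nlrc5 at a log2 fold change of 0.50 and Tap1 at 0.17. The antigen presentation list passed without wild-type library 4 or heterozygous library 4 (adjusted p = 0.00236 and 0.002, median 0.19 in both), and its median was 0.04 without wild-type library 2 (adjusted p = 0.620). For the cytokine, monocyte and stem cell lists the median was below 0 while camera's direction was upward. Without 1 library their medians ran from -0.08 to 0.07, -0.11 to 0.08 and -0.15 to 0.04, above 0 without wild-type library 2 and heterozygous libraries 3 and 4 in turn for cytokines, without wild-type libraries 1, 3 and 4 and heterozygous library 3 in turn for monocytes, and without wild-type library 4 and heterozygous library 4 in turn for stem cells. No member of the cytokine and antigen presentation lists passed over all genes tested or adjusted over the list alone.

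Among metabolic and growth lists, 4 passed with the preset correlation and lost the call with the estimated one. The medians on the log2(TPM + 1) scale are to be read against 0.052, the median over all genes tested on that scale. Of 25 oxidative stress genes, 20 had lower values, with a median log2 fold change of -0.15 (13 of 25 and -0.05 on the log2(TPM + 1) scale; camera adjusted p = 0.0159, and adjusted p = 0.713 with an estimated correlation). The ferritin light chain gene Ftl1 averaged 7274 CPM ± 632 in wild-type and 6227 CPM ± 567 in heterozygous libraries, and the peroxidase gene Gpx1 1558 CPM ± 209 and 1308 CPM ± 133 (SD, n = 4 each). Of 41 genes of oxidative phosphorylation, 32 had lower values (median -0.08, or 13 of 41 and 0.025 on the log2(TPM + 1) scale, camera adjusted p = 0.0128, and adjusted p = 0.713 with an estimated correlation), with Atp5d at a log2 fold change of -0.35. Of 23 glycolysis genes, 18 had lower values (median -0.13, or 10 of 21 and 0.0021 on the log2(TPM + 1) scale, camera adjusted p = 0.0437, and adjusted p = 0.713 with an estimated correlation), with Pfkfb3 at -0.25 and Hif1a at 0.34. Of 39 cell cycle genes, 25 had higher values (median 0.14, camera adjusted p = 0.0373, and adjusted p = 0.713 with an estimated correlation), with Aurkb at 0.176 CPM ± 0.039 and 0.394 CPM ± 0.071 (SD, n = 4 each), a gene that lies within 20 Mb of Trp53. Of 23 genes of the unfolded protein and heat shock responses, 16 had lower values (median -0.05, or 0.04 on the log2(TPM + 1) scale and 0.0086 without heterozygous library 4; camera adjusted p = 0.451). No member of these 5 lists passed over all genes tested or adjusted over the list alone. Without wild-type library 3 or 4 or heterozygous library 4, none of the 4 lists passed, and the cell cycle list also failed without heterozygous library 3. Without heterozygous library 4 the medians of the cell cycle, oxidative stress and glycolysis lists were 0.04, -0.05 and -0.06, and without wild-type library 3 that of glycolysis was -0.05. Over the 8 fits they ran to 0.20, -0.17 and -0.20, and that of oxidative phosphorylation from -0.12 to -0.06.

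Among markers of RNA quality and of other blood cells, 5 lists passed with the preset correlation. Of 52 genes of cytosolic ribosomal proteins, 48 had lower values (median -0.12, or 27 of 50 and -0.017 on the log2(TPM + 1) scale, camera adjusted p = 0.00122, and adjusted p = 0.713 with an estimated correlation), a call lost without wild-type library 4 (median -0.04). Of 13 mitochondrially encoded transcripts, 12 had higher values (median 0.14, camera adjusted p = 0.0308, and adjusted p = 0.713 with an estimated correlation). Of 16 platelet genes, 15 had lower values (median -0.32, or 14 of 15 and -0.10 on the log2(TPM + 1) scale, camera adjusted p = 0.0165, and adjusted p = 0.713 with an estimated correlation), with Vwf at 6.87 CPM ± 2.52 and 5.16 CPM ± 0.66 (SD, n = 4 each). Of 14 B cell genes, 13 had higher values (median 0.17, camera adjusted p = 0.0165, and adjusted p = 0.713 with an estimated correlation), with Cd22 at 1.87 CPM ± 0.19 and 2.52 CPM ± 0.44 (SD, n = 4 each). Of 18 T and NK cell genes, 15 had higher values (median 0.28, camera adjusted p = 0.0295, and adjusted p = 0.713 with an estimated correlation), with Lck at 0.255 CPM ± 0.042 and 0.552 CPM ± 0.247 (SD, n = 4 each). The calls of the mitochondrial, platelet, B cell and T cell lists held in 3, 4, 4 and 5 of the 8 fits that left out 1 library, and all 4 were lost without heterozygous library 4. The median of the platelet list ran from -0.49 to 0.02, above 0 without wild-type library 4, and that of the mitochondrial list from -0.03 to 0.30, below 0 without wild-type library 1, whereas those of the B cell and T cell lists stayed above 0, from 0.01 to 0.49 and from 0.02 to 0.55. Immediate early genes (camera adjusted p = 0.0977), erythroid genes (0.116), eosinophil, basophil and mast cell genes (0.790) and stem and progenitor genes (0.893) did not pass. The immediate early list passed without wild-type library 3 or heterozygous library 2 or 3 (medians -0.27, -0.25 and -0.24, lowest adjusted p = 0.014) and had a median of -0.03 without wild-type library 2. The erythroid list passed without wild-type library 4 (median 0.59, adjusted p = 2.9e-05) or heterozygous library 2 (0.39, adjusted p = 0.000376) and had a median of 0.05 without wild-type library 1. No member of these 9 lists, nor of the monocyte list, passed over all genes tested or adjusted over the list alone. In all, 11 of 25 lists passed with the preset correlation, 5 upward and 6 downward, and 0 with an estimated correlation or with fry's directional or mixed test (lowest adjusted p = 0.713, 0.708 and 0.730).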

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

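The tests of deeper sequencing in the paragraph on silent genes were chosen after the result was seen. In 304 groups of 4 libraries, 14 values stood apart from the 3 other libraries of their genotype by Dixon's test at the 95% level, where chance gives about 15.2.

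Wild-type library 1 had 22200 genes with at least 1 count, against 18400 to 19000 in the other wild-type libraries, and heterozygous library 4 was also high with 21798. Protein-coding genes that averaged under 0.02 CPM in the remaining libraries took 144 CPM in sum in wild-type library 1 and 115 in heterozygous library 4, against 24.8 to 43.1 in the other 6. Deeper sequencing is argued against, since 3 libraries with more counts than both had a rate of at most 43.1 CPM. RNA of another tissue is argued against too, because the 10 highest of these genes held 1.82% of the counts. Genomic DNA carried into the libraries stays open as a candidate source: X-linked silent genes, with 1 copy in males, had 0.577 times the counts per kb of autosomal ones (95% bootstrap interval 0.489 to 0.676), where DNA of a male would give about 0.5, and no biological explanation was tested because the 2 libraries belong to different genotypes.

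Markers of T and NK cells took 0.0014% of the counts in wild-type library 2, below 0.0017% in each other wild-type library. These shares were rounded to the digits shown before the test, so the flag may come from rounding. The score of the unfolded protein and heat shock list was -0.181 in wild-type library 3, against 0.0558 to 0.104 in the others, and -0.221 in heterozygous library 4, against 0.0338 to 0.0598. Hspe1, a mitochondrial chaperonin gene of that list, was at 1.64 CPM in wild-type library 2 (others 0.979 to 1.08) and at 2.12 CPM in heterozygous library 4 (others 1.3 to 1.38). The single wild-type count of Capn11 put wild-type library 1 at 0.0151 CPM, with the others at 0.

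Among granule genes, Serpinb1a was at 34.5 CPM in heterozygous library 1 (others 22.9 to 23.9) and Prtn3 at 3.97 CPM in heterozygous library 3 (others 1.56 to 1.85). Mcm6 was at 0.13 CPM in wild-type library 4 (others 0.261 to 0.273) and Mcemp1 at 1580 CPM in wild-type library 3 (others 1250 to 1300). In heterozygous library 3, Rpl13 was at 42 CPM (others 33.6 to 34.7) and Cd79a at 3.23 CPM (others 1.8 to 2.02). Csf2ra was at 179 CPM in heterozygous library 1, with 282 to 300 in the other heterozygous libraries.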

How the results depend on the processing

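The fit without wild-type library 1 and heterozygous library 4 together, and the leaving out of single libraries for library composition and transcripts, were chosen after seeing the data. The count of 4 changed genes was within 1.5 times under median-ratio size factors (4), length-scaled counts (3), non-robust fits (3), without hemoglobin and mitochondrial genes (4) and at a threshold of 0.1 (5). It was 20 without the low-count filter, 14 with DESeq2 and 9 with limma voom, and the 4 genes were among those called in each of these 3 settings. It was 1 with a minimum of 5 CPM, where 6544 genes were tested and Capn11 and Eps8l1 lie below the minimum. Sgip1 and Gm1821 lie above it, and only 1 of them kept its call. The count was also 1 with limma on log2(TPM + 1) and on log2(TPM + 0.1). Without wild-type library 1 and heterozygous library 4 together it was 0 with edgeR, with 810 genes at an unadjusted p under 0.05, on 3 libraries per genotype. It ran from 1 to 3 when 1 library was left out: 1 without wild-type library 1, 2 or 4 or heterozygous library 2 or 3, 2 without wild-type library 3, and 3 without heterozygous library 1 or 4. With the replicate number as a replicate block it was 1, and the log2 fold change of Trp53 was -0.79. The numbers are not stated to pair the mice. The correlations of deviations between libraries with the same number were -0.11, -0.021, 0.12 and -0.38, and 1 of 4 wild-type libraries correlated best with its own number. These few values gave no sign of pairing but cannot exclude it.

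The log2 fold change of Trp53 ran from -0.92 to -0.49 over 18 alternatives, from -0.88 to -0.67 when 1 library was left out, and passed the threshold only with DESeq2 (-0.79). The count of 11 lists was 9 to 14 under 6 settings. It was 3 with a minimum of 5 CPM, 5 with voom, 5 with limma on log2(TPM + 1), and 0 with an estimated correlation, with fry's directional test and with fry's mixed test. It ran from 3 to 14 when 1 library was left out, with 5 without wild-type library 3, 6 without wild-type library 4 and 3 without heterozygous library 4. The count of library measures that differed was 0 in these fits too, which says little about stability, since no single measure can pass adjustment over 17 with so few libraries. Where an estimated correlation or a smaller number of genes or libraries does not account for a change, the cause was not tested.

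Of 2021 values of single named genes, 1966 kept direction and side of the threshold, 32 lost a call, 20 gained one and 3 changed sign without a call in either fit. Depth limits how far the level of a rare transcript can be bounded: Capn11-201 had 0 counts in wild-type libraries, and its bound rests on a floor of 3 counts over the group.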

Other observations

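The counts around Trp53 were chosen after low p-values near the gene had been seen, and so were the tests of a dose effect acting anywhere, of monocytes and of the ratio of shares between splits.

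Several genes near Trp53 that belong to none of the lists differed without overlap between genotypes. Gm12250, annotated as a processed pseudogene, averaged 124 CPM in wild-type and 216 CPM in heterozygous libraries, the ubiquitin ligase gene Trim11 140 and 108 CPM, the guanylate kinase gene Guk1 9.23 and 6.54 CPM, and the copper chaperone gene Atox1 85.7 and 65.9 CPM. Heterozygous libraries 1 to 4, with Gm12250 at 252, 268, 193 and 153 CPM, ranked as by their interferon list scores. Wild-type libraries 1 and 3 ranked the other way round. Gemin5, of the SMN complex, averaged 0.586 and 1.36 CPM, and the histone gene Hist3h2a 68.8 and 47.4 CPM. None of the 6 passed adjustment in edgeR's test over all genes, and they were named after their values were seen. Retn, which encodes the hormone resistin and lies on chromosome 8, averaged 32.6 CPM ± 1.2 and 23.8 CPM ± 3.4 (SD, n = 4 each) without overlap (edgeR adjusted p = 0.873) and was likewise named afterwards.

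The genotype split of the libraries called 4 genes, and 2 of the 35 splits into 4 and 4 called as many, so chance cannot be excluded for the count. The highest other split, with 115 genes, sets wild-type libraries 1, 2 and 3 and heterozygous library 4 against the rest. It shares 0 called genes with the genotype split, 1 of its 115 genes is on the interferon list, and 109 were higher in the 4 named libraries. These 4 include both libraries with raised counts of silent genes, wild-type library 1 at 144 and heterozygous library 4 at 115 CPM. So many calls point to a structure of the samples, whose origin was not tested. An exchange of wild-type library 4 and heterozygous library 4 would make this split. Capn11 was at 0 CPM in the former and 1.28 in the latter, as in their labelled groups, but the labelled split itself picked that gene. Trp53, named in advance, was at 6.53 CPM in wild-type library 4, with the other wild-type libraries at 5.54 to 6.33. It was at 4.30 CPM in heterozygous library 4, with the other heterozygous libraries at 2.69 to 3.70. For the 11 lists, 8 of the 35 splits passed as many (highest other 15), and chance cannot be excluded. Every other split passed at least 2 lists with the preset correlation, so a list that passes in this way is not evidence of a genotype effect by itself. For the 4 transcripts, 1 of the 35 splits, the genotype itself, gave as many (highest other 3). The margin is 1 transcript, and the 4 transcripts come from 3 genes. The test per transcript was added after the data were examined, so the count is not taken to exclude chance. In 4 of the 8 fits without 1 library 0 transcripts passed, although the levels of the genotypes lay apart in all 8 libraries: Nlrp1b-204 was at 3.44 to 5.71 CPM in wild-type and at 0 in heterozygous libraries, and Capn11-201 at 0 and at 1.21 to 1.68 CPM.

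The first pattern is the crowding of low p-values around Trp53, 17 genes within 20 Mb. Higher expression of the genes there is argued against, since none of 10000 random sets matched on mean expression held as many (share 1e-04, the smallest they can give; highest set 13). With its 17 genes, Trp53 included, the window held 4.63 times the expected number. The central 95% of the matched sets ended at 2.18. This count is the pattern itself, and no independent value was used. It therefore cannot decide whether a lower Trp53 dose acting anywhere in the genome is the whole cause. As a plain count, 2 of the 35 splits had 17 or more such genes (highest other 21), so chance cannot be excluded for the count. That other split is the one with 115 called genes, and it showed little crowding, with a p under 0.01 for 4.48% of the genes tested in the window and 4.03% elsewhere, a ratio of 1.11. By this ratio of shares 1 of the 35 splits, the genotype itself, had one as large (4.76, highest other 4.55, from 3 genes in the window). The ratio was chosen after the plain count, which itself followed a look at the data, so it is not taken to exclude chance. DNA of another strain or another local change carried with the targeted allele remains a hypothesis: the rest of chromosome 11 held 1.17 times the expected genes, with a share of 0.403 of matched sets as high, and reads of a variant allele may also be assigned to other transcripts, as with the Nlrp1b pair or with Gm1821 and Ubb, which was not tested on sequence.

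The second pattern is the higher interferon list in heterozygous mice. The libraries with raised counts of silent genes are argued against, since the median log2 fold change was 0.406 without them and 0.362 with them. Variation between mice that the whole list shares stays open, as the exact permutation p of the list mean was 0.114 and heterozygous library 4 lay below wild-type libraries 2 and 4. More monocytes in the sort cannot be told apart from it: the mean log2 fold change of the monocyte and macrophage list was 0.072 with a standard error of 0.0664 over genes. The sort was for neutrophils, but markers of monocytes and macrophages were still counted. Their share of the counts was 0.376% in wild-type and 0.365% in heterozygous libraries, with Csf2ra at 386 and 261 CPM and Ctss at 419 and 510 CPM. The lists of B cells (median 0.17) and of T and NK cells (0.28) were higher too and that of platelets lower (-0.32), and other cells than monocytes were not tested as a source. An effect of the genotype on interferon signalling after doxorubicin also stays open and was not tested apart from these.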
